A study of Homo sapiens with 16 samples.

How the data were processed

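RNA of 16 samples was hybridised to Illumina bead arrays, 1 array per sample. The labels give 2 replicates for each of 8 groups, a Dox concentration of 2.5 µg/mL over 6 days, a passage at day 3 and serum-free medium from day 4. Whether the untreated arms and the overexpression lines had the serum-free step is not given in the sources used here. Per the labels' protocols, cDNA was made from 100 ng of total RNA, with a RIN of 9.5, and biotinylated cRNA was prepared.

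The scanner table deposited by the authors holds an intensity per probe and array with a detection p-value, and the submitters' processing notes name GenomeStudio 1.6.0 without saying what it was used for. Its intensities were neither background-subtracted nor scaled between arrays: all were positive, and array medians ran from 78.0 to 105.4. The authors' series matrix, deposited as linear intensities, has medians of 133.6 to 134.5 and a lowest value near 100 on each array. Its normalization is not given in the sources used here. Its values are compressed near the background, so its fold changes of dim probes are smaller.

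The rows of both tables were compared through a smooth map of each array's scanner signal onto its series matrix value. For 1054 of 24530 probes (4.30%) the median gap over the arrays exceeded 0.3 on the log2 scale. For 994 of the 996 of these that have a gene symbol, the values stood under another probe of the same gene, so the tables interchange probe identifiers within genes. Most gene-level values are little affected, but 4 named results, of CAPSL and HK1, changed direction with the series matrix. The probe behind a gene is uncertain for 434 of 9654 tested items. No linker histone H1 probe was among them. Which table has the right identifiers is not known. The scanner table, whose detection p-values stand beside its own signals, was used throughout.

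Probes were named from the platform annotation: 23266 had 1 symbol, none had several and 1264 were unnamed. Symbols were checked against a gene table through the gene identifiers: 23142 probes matched and 0 symbols changed. Intensities were background-corrected by normexp with negative controls inferred from the detection p-values, with an offset of 16, quantile-normalized and set on the log2 scale (neqc in limma 3.58.1, R 4.3.3). Probes detected at p under 0.01 on at least 2 of 16 arrays were kept, 11258 in all, and 1 probe per symbol, the one of highest mean, was tested. That left 9654 items, 9172 named genes and 482 unnamed probes. For a gene undetected on all arrays of a group, the brighter group was set against the higher of each array's lowest detected signal and the probe's own value, and the result is written as "at least N-fold".

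One limma model with a mean per group was fitted to all 16 arrays (lmFit, contrasts.fit and eBayes with a trend, 8 residual degrees of freedom), with Benjamini-Hochberg adjustment over the items and a threshold of adjusted p under 0.05. Contrasts were Dox against no Dox in each hairpin line, the differences between these effects, K26A against WT, each overexpression line against Ctrl, and the untreated lines against Ctrl. Before the data were examined, 27 gene lists were fixed. The 22 with at least 5 tested genes were tested by camera with a preset correlation of 0.01, adjusted over 176 tests of 8 contrasts, and separately over 22 tests for the difference of sh225 and sh120. Of 75 calls in the former 8 contrasts, 51 held with an estimated correlation. Lists of H1 variants and of basal, leukocyte, endothelial and germline markers had 3 or 4 tested genes and were not tested. Of 4 germline genes, 2 fell with Dox in the sh225 line (3 adjusted over the list alone), 3 in the sh120 line, 1 in the Ctrl line (3 adjusted over the list alone) and 3 in WT against Ctrl. Of 4 basal markers, 2 rose and 1 fell in the sh225 line (2 and 2 adjusted over the list alone), and 1 rose in the sh120 line, in the Ctrl line and in WT against Ctrl (2 adjusted over the list alone in the last pair). Of 3 leukocyte markers, 1 fell in the sh225 line and 1 rose in the sh120 line, in WT against Ctrl and in K26A against WT. Of 3 endothelial markers, 1 fell in the sh225 line and 1 rose in WT against Ctrl (1 higher and 1 lower adjusted over the list alone). Counts of list members adjusted over the list alone are given where they differ from those over all genes.

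Lists not called in any of the 5 comparisons described at length were interferons and nucleic acid sensors, mitochondrial genes and secreted glycoproteins. With Dox in the sh225 line, 8 of 55 mitochondrial genes rose and 5 fell (7 and 2 adjusted over the list alone, adjusted p = 0.887), and 10 of 31 secreted glycoproteins rose and 6 fell (adjusted p = 0.115). Genes to name were fixed by rule before the data were examined. For the 3 Dox effects, K26A against WT and WT against Ctrl these were the 10 largest rises and falls called with both arrays of a group above both of the other. For the differences of sh225 from Ctrl and from sh120 they were the 5 largest each way. In every contrast the H1 genes, up to 4 called members of each called list and up to 3 members of other lists were added. Only some of these are printed, chosen after their values were seen, and genes undetected in both groups were left out.

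The procedure was tested on simulated data of 9654 genes for the sh225 Dox effect. It recovered 35.8% of 67 genes changed by 0.5 on the log2 scale, 91.0% of 67 changed by 1 and 100% of 66 changed by 2, with 9 false calls among 160. The noise was independent between genes and few genes were changed. The real sh225 Dox effect called 35.55% of items, so these rates may not carry over to it. Alternatives covered background correction, normalization, the series matrix, probe filters, probes per gene, variance model, array weights, the replicate number as a block, samples in the fit, a fold threshold, label sets, another control and leaving out each array. Figures were drawn with matplotlib 3.10.9.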

Results

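Gene expression was measured with Illumina bead arrays of 24530 probes in T47D-MTVL cells, a human breast cancer line of luminal type that carries an integrated luciferase reporter under a viral promoter. The 16 arrays fell into 8 groups of 2. Lines with a doxycycline (Dox) inducible hairpin were grown with or without Dox for 6 days: sh120, with a hairpin against the linker histone H1.4, sh225, with a hairpin against several linker histone H1 variants, and Ctrl, with a random hairpin. Another pair of lines, grown without treatment, overexpressed HA-tagged H1.4, either WT or the K26A mutant (group K26). Linker histones bind the DNA that enters and leaves the nucleosome. Between 9477 and 10286 probes per array were detected, and replicates correlated at r = 0.989 to 0.994 across genes. The number of arrays limits the precision: the median SE of a log2 fold change between 2 groups was 0.152. The labels do not say that replicates were separate cultures, so p-values measure the spread between arrays, which may be technical.

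The H1 transcripts were examined first, because they check the labels. The H1-2 transcript fell by 2.75 ± 0.15 (log2 fold change ± SE, adjusted p = 6.09e-11, n = 2 per group) with Dox in the sh225 line, from a mean of 8.83 to 6.08, and was detected on 1 of 2 arrays with Dox. H1-2 did not pass the test in the sh120 line (0.30 ± 0.15, adjusted p = 0.169). In the Ctrl line it rose by 0.55 ± 0.15 (adjusted p = 0.0473), a call lost under 10 of 15 alternatives. H1-10, which encodes the H1x variant, fell by 0.52 ± 0.14 in the sh225 line (adjusted p = 0.00768), a call lost without sh225 replicate 2 (adjusted p = 0.0911) or sh225_Dox replicate 2 (0.0559). It fell by 0.45 ± 0.14 in the sh120 line (adjusted p = 0.0357), a call lost under 6 of 16 alternatives, with the highest adjusted p, 0.249, without sh120_Dox replicate 1. In the Ctrl line H1-10 did not pass the test (-0.27 ± 0.14, adjusted p = 0.360). Neither hairpin line's H1-10 effect differed from that of Ctrl in the test of the difference (-0.25 ± 0.20, adjusted p = 0.450, for sh225 and -0.18 ± 0.20, adjusted p = 0.761, for sh120). The H1-1, H1-3, H1-4 and H1-5 probes were not detected on any array of the hairpin lines, so depletion of these variants, including H1.4 in the sh120 line, could not be checked. H1-4 was detected on both arrays of the WT and both of the K26 group, and was at least 4.33-fold higher in WT than in Ctrl (adjusted p = 3.24e-11). Between K26A and WT it did not pass the test (-0.33 ± 0.17, adjusted p = 0.171), but did so under 4 alternatives, among them no background correction (adjusted p = 0.00505). Whether the H1-4 probe lies in the sequence that the vector carries is not given in the sources used here. H1-2 was also higher in WT than in Ctrl, so the H1-4 signal cannot be assigned to the vector rather than the cell's own gene. The authors' series matrix gave -1.57 for H1-2 in the sh225 line, and smaller fold changes for other genes of low signal as well.

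**Figure D1:**
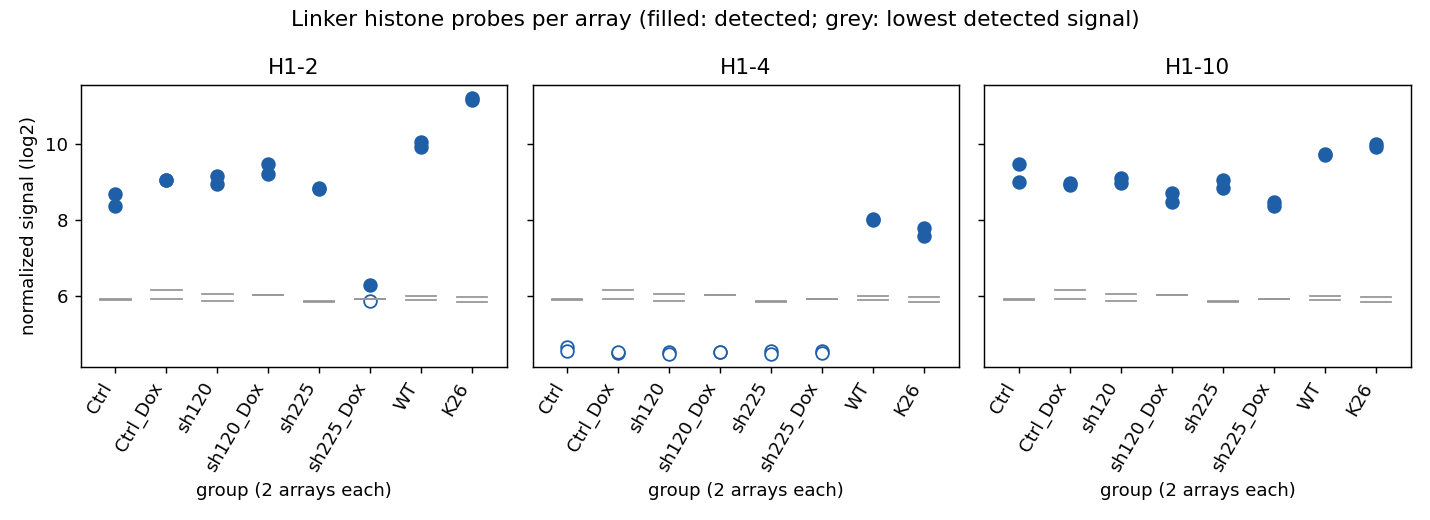
Normalized log2 signal (vertical axis) of the H1-2, H1-4 and H1-10 probes on each of 16 arrays, by group (horizontal axis). Filled points were detected, open points were not, and grey lines mark each array's lowest detected signal. H1-2 fell from a mean of 8.83 to 6.08 with Dox in the sh225 line, and H1-4 was detected in the WT and K26 groups only.

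Of 9654 genes and unnamed probes tested, 3432 changed with Dox in the sh225 line (1650 higher, 1782 lower), 1593 in the sh120 line (779 higher, 814 lower) and 288 in the Ctrl line (140 higher, 148 lower). Changes of at least 2-fold were found for 634, 101 and 58 of these. The K26A and WT lines differed in 2208 genes. The untreated sh225 and sh120 lines differed from the untreated Ctrl line in 44 and 2 genes.

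**Figure D2:**
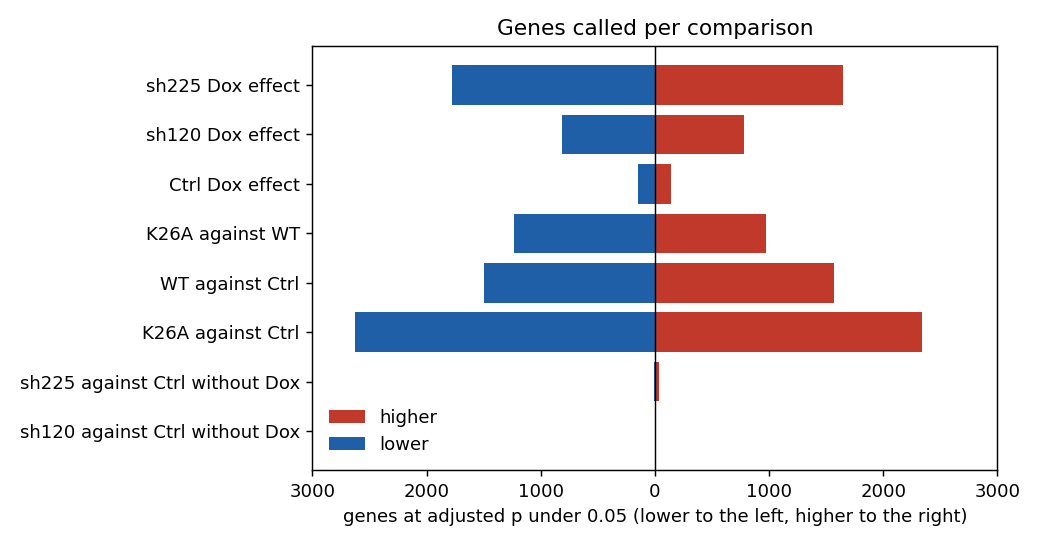
Number of genes at adjusted p under 0.05 (horizontal axis, starting at 0 in both directions) in 8 comparisons (vertical axis), higher to the right and lower to the left. The bars reach from 4962 genes in total for K26A against Ctrl to 2 genes for sh120 against Ctrl without Dox.

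The comparison of the sh225 line with and without Dox asks what follows expression of the hairpin against several H1 variants, together with Dox itself. Interferon-stimulated genes, which cells switch on in answer to interferon or foreign nucleic acid, rose together: 49 of 60 rose and 1 fell (50 and 1 adjusted over the list alone), with a mean log2 fold change of 1.61 (camera adjusted p = 2.34e-28). IFIT2, OASL and IFIT3, undetected without Dox, were at least 35.7-fold, 34.1-fold and 30.9-fold higher, and IFI44 at least 14.9-fold. IFI27 rose by 4.80 ± 0.17 (log2 ± SE), IFIT1 by 4.37 ± 0.16 and ISG15, a ubiquitin-like modifier, by 4.31 ± 0.21. Antigen presentation genes followed, with 11 of 18 higher (12 adjusted over the list alone) and 2 lower (camera adjusted p = 7.90e-05). They included the class II gene HLA-DRA (2.37 ± 0.19) and the invariant chain CD74 (1.65 ± 0.16). Of NF-kappaB targets and cytokines, 6 of 13 rose (adjusted p = 0.00429), among them the feedback inhibitor TNFAIP3 (1.30 ± 0.15). The list of interferon genes and nucleic acid sensors was not called (3 of 14 higher and 2 lower, adjusted p = 0.213), but its interferon gene IFNL1, undetected without Dox, was at least 1.71-fold higher (adjusted p = 1.14e-07).

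Cell cycle genes fell in the sh225 line. Of 44 genes of G2/M and mitosis 43 fell (43 adjusted over the list alone), with a mean log2 fold change of -1.47 (camera adjusted p = 1.54e-33). The kinases AURKB and CDK1 fell by 2.30 ± 0.16 and 2.21 ± 0.14, the topoisomerase TOP2A by 2.20 ± 0.13 and the cyclin CCNB2 by 2.15 ± 0.11. Of 39 genes of G1/S and DNA replication 32 fell (33 adjusted over the list alone, camera adjusted p = 6.79e-20), with thymidine kinase TK1 down by 2.05 ± 0.10 and MCM10 by 1.76 ± 0.14. Of 18 DNA repair and checkpoint genes 13 fell (14 adjusted over the list alone, camera adjusted p = 3.15e-07), including the exonuclease EXO1 (-1.85 ± 0.13) and FANCI (-1.37 ± 0.18). Of 31 heterochromatin and chromatin regulators 12 fell and 1 rose (adjusted p = 0.0065). That call was lost with an estimated correlation (adjusted p = 0.0532). HMGB2 fell by 1.02 ± 0.16.

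Sterol synthesis genes also fell with Dox in the sh225 line: 16 of 23 were lower and 1 higher (adjusted p = 8.85e-07). The epoxidase SQLE fell by 1.54 ± 0.14 and MVD by 1.52 ± 0.18, and INSIG1 was at least 2.73-fold lower and undetected with Dox. Higher lists were p53 targets (10 of 19 higher and 2 lower, adjusted p = 0.00203), with the nuclease AEN at 1.25 ± 0.12, and serum response genes (14 of 26 higher and 2 lower, adjusted p = 2.84e-05), with JUN at 1.23 ± 0.12. Among apoptosis genes 11 of 25 rose and 1 fell (11 and 2 adjusted over the list alone, adjusted p = 0.0109, and 0.103 with probes detected on all arrays), led by the inflammatory caspase CASP1 (1.59 ± 0.16). The apoptosis list was not called in the difference of the sh225 and Ctrl Dox effects (camera adjusted p = 0.0611). Among cytosolic ribosomal proteins 14 of 42 rose (12 adjusted over the list alone, adjusted p = 0.00753), with RPS23 at 0.85 ± 0.11. Metallothionein and oxidative stress genes rose in 9 of 15 cases and fell in 3 (10 and 3 adjusted over the list alone). The adjusted p = 0.00271 went to 0.0714 with probes detected on all arrays, and the adjusted p was 0.0618 with an estimated correlation. MT1X, a metal-binding protein, rose by 2.10 ± 0.12. Of 37 ATF4 and unfolded protein response genes 15 rose and 3 fell (adjusted p = 0.00754, and adjusted p = 0.147 with an estimated correlation). Outside these lists, the largest falls included HOATZ, which fell by 3.14 ± 0.16 and was detected on 1 of 2 arrays with Dox, ROPN1L (-2.53 ± 0.18), RIPPLY3 (-2.46 ± 0.14) and CDC20B (-2.43 ± 0.18). CAPSL was at least 4.91-fold lower and NMU, a neuropeptide, at least 3.79-fold lower. In the series matrix, where the rows of the CAPSL probes are interchanged, the log2 change of CAPSL was 0.078, and it was -1.24 with rows aligned. Leaving out sh225 replicate 2 gave 2266 called genes.

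**Figure D3:**
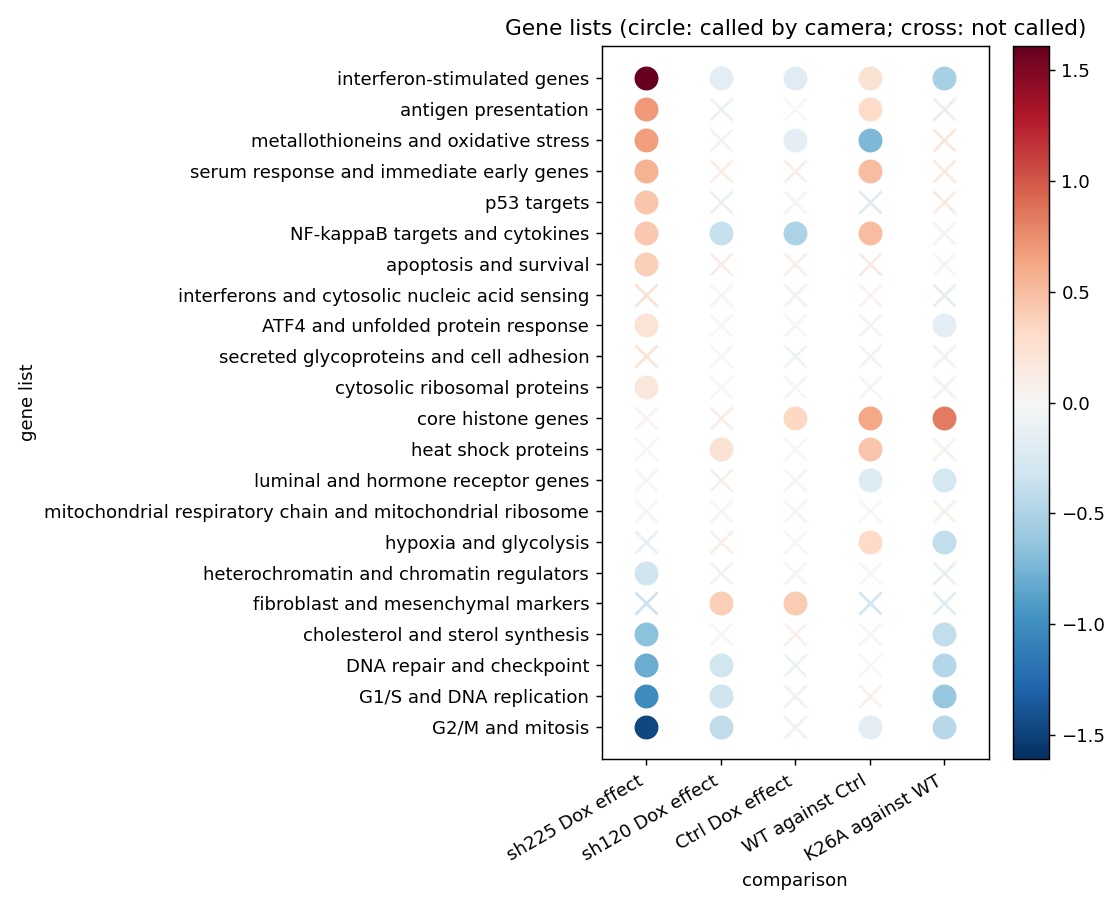
Mean log2 fold change (colour) of 22 gene lists (vertical axis) in 5 comparisons (horizontal axis), with circles for lists called by camera and crosses for the others. Interferon-stimulated genes had a mean of 1.61 and G2/M genes one of -1.47 with Dox in the sh225 line.

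The sh120 line with and without Dox asks what follows expression of the hairpin against H1.4, together with Dox itself. The interferon-stimulated, NF-kappaB and fibroblast lists below were called in the same direction in the Ctrl line. They were not called in the difference of the sh120 and Ctrl Dox effects (camera adjusted p = 0.563, 0.218 and 0.897). Cell cycle lists were lower in the sh120 line too, with smaller changes than in the sh225 line. Of 44 G2/M genes 22 fell (29 adjusted over the list alone, mean -0.41, camera adjusted p = 1.65e-10), including AURKB (-0.98 ± 0.16) and the transcription factor FOXM1 (-0.98 ± 0.18). Of 39 G1/S genes 18 fell (21 lower and 1 higher adjusted over the list alone, adjusted p = 7.33e-08), including the ligase LIG1 (-0.75 ± 0.15). PCNA fell by 0.81 ± 0.13, but its other probes went from -0.66 to 0.36. Of 18 DNA repair genes 7 fell (adjusted p = 0.00128). Of 60 interferon-stimulated genes 11 fell and 1 rose (11 and 1 adjusted over the list alone, adjusted p = 0.00526). IRF9, a factor of the interferon response, fell by 1.25 ± 0.15. Of 13 NF-kappaB targets 5 fell (6 adjusted over the list alone, adjusted p = 0.00754, and 0.150 with probes detected on all arrays), among them the chemokine CCL20 (-1.33 ± 0.23). Heat shock genes rose in 4 of 15 cases (adjusted p = 0.00924, and adjusted p = 0.166 with an estimated correlation), with HSPB8 at 0.94 ± 0.15. The fibroblast list was called (adjusted p = 0.0291, and adjusted p = 0.0937 with an estimated correlation) with 1 of its 6 genes higher (2 adjusted over the list alone), S100A4 (1.09 ± 0.12), a calcium-binding protein also made by epithelial cells. That call was lost without sh120 replicate 1 (adjusted p = 0.0521), without sh120_Dox replicate 2 (0.0650) and without a filter (0.260).

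The largest single rises in the sh120 line were those of GCGR, the glucagon receptor, at least 3.17-fold, and MYH11, a smooth muscle myosin, by 2.57 ± 0.19 (detected on 1 of 2 arrays without Dox). VTCN1, an immune checkpoint ligand, rose by 2.19 ± 0.17 and FOXN4, a transcription factor, by 1.89 ± 0.15. The largest falls included SAA1 (-1.96 ± 0.12), the protease inhibitor SLPI (-1.69 ± 0.16) and LCN2 (-1.56 ± 0.08). The probes of SAA1 may also read its near-identical copies. AKR1C2, a steroid-metabolising enzyme, was at least 1.88-fold lower. VTCN1, SAA1, AKR1C2 and LCN2 moved in the same direction with Dox in the Ctrl line. Ctrl values of the other genes named in this paragraph are not given here. The count of 1593 genes was 651 without sh120 replicate 1, 670 without sh120 replicate 2, 722 without sh120_Dox replicate 1 and 825 without sh120_Dox replicate 2, and was 1059 at a log2 change of at least 0.5.

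The Ctrl line with and without Dox gives the background of Dox and of the inducible system. AKR1C2 was at least 3.42-fold lower, SAA1 fell by 2.05 ± 0.12, CCL20 by 2.04 ± 0.23, ORM1 by 1.95 ± 0.15 and the complement factor CFB by 1.52 ± 0.12. VTCN1 rose by 1.93 ± 0.17, KRT80, a keratin, by 1.49 ± 0.11 and ADM, a peptide hormone, by 1.19 ± 0.10. Of 60 interferon-stimulated genes 8 fell (11 adjusted over the list alone, mean -0.19, adjusted p = 3.49e-05), including IRF9 (-1.63 ± 0.15) and MX1 (-1.02 ± 0.10). Of 13 NF-kappaB targets 5 fell (6 lower and 1 higher adjusted over the list alone, adjusted p = 8.85e-07), with SOD2 at -0.81 ± 0.11. Of 15 metallothionein and oxidative stress genes 5 fell and 2 rose (7 and 5 adjusted over the list alone, adjusted p = 0.0232, and adjusted p = 0.133 with an estimated correlation), with the reductase NQO1 at -1.11 ± 0.09. That call was lost without Ctrl replicate 2 (adjusted p = 0.0530) and without a filter (0.158). Core histone genes rose in 3 of 22 cases (7 adjusted over the list alone, adjusted p = 3.48e-07, and adjusted p = 0.0616 with an estimated correlation), led by H4C8 (0.90 ± 0.13). S100A4 rose by 1.02 ± 0.12 (fibroblast list, 1 of 6 higher, 2 adjusted over the list alone, adjusted p = 0.00129, and 0.131 without a filter). Neither cell cycle list was called (adjusted p = 0.130 for G1/S and 0.0725 for G2/M). The count of 288 fell to 133 without Ctrl replicate 1, 136 without Ctrl_Dox replicate 1 and 135 without Ctrl_Dox replicate 2.

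The overlap of the sh120 and Ctrl lists of called genes was 81 higher and 97 lower, against 11.3 and 12.5 for independent lists of the same sizes. The sh225 and sh120 lists shared 321 higher and 466 lower genes, against 133.1 and 150.3. The sh225 and Ctrl lists shared 69 higher and 68 lower genes, against 23.9 and 27.3. These comparisons share no arrays. They do share the Dox treatment, so the overlap of sh225 and sh120 cannot be credited to the hairpins alone. The test of the difference itself called 1571 genes between the Dox effects of the sh225 and Ctrl lines (643 higher, 928 lower) and 1347 between those of sh225 and sh120. It called 41 between sh120 and Ctrl (34 higher, 7 lower). Interferon-stimulated genes were higher in the sh225 line than in Ctrl by a mean difference of 1.80 (47 of 60 higher and 1 lower, 51 and 1 adjusted over the list alone, adjusted p = 1.75e-39). Thymidine kinase TK1 differed by -2.06 ± 0.15 and H1-2 by -3.30 ± 0.21. The chemokine CCL20 differed by 2.14 ± 0.33, for the most part through its fall with Dox in the Ctrl line. For sh120 against Ctrl, G2/M genes were lower by a mean difference of -0.33 (adjusted p = 8.48e-09) and G1/S genes by -0.25 (adjusted p = 2.41e-06), with 7 and 6 genes lower adjusted over the list alone, and 1 and 0 over all genes by limma. The count of 41 went to 1 without sh120_Dox replicate 2 and to between 6 and 26 without any other of the 8 arrays.

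**Figure D4:**
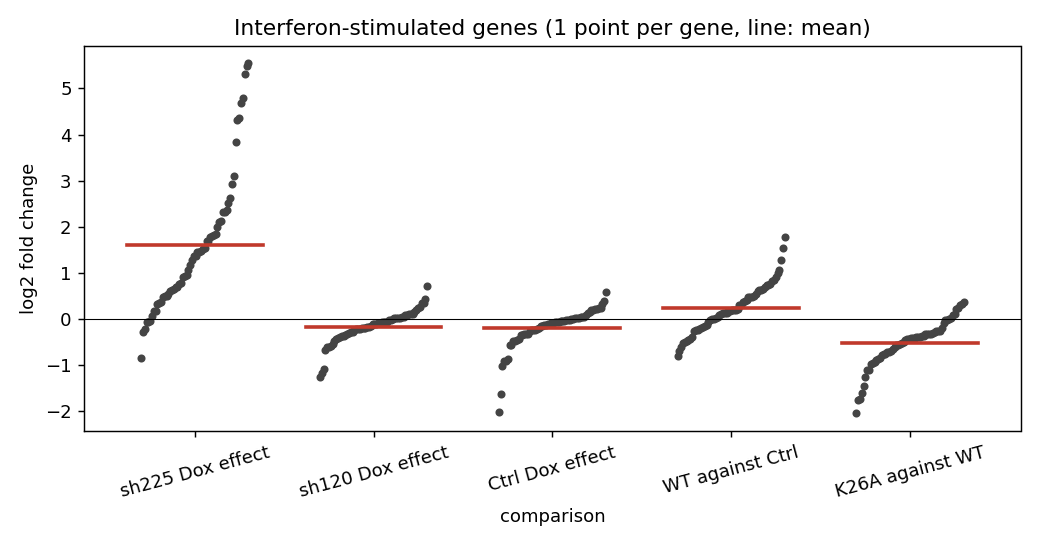
Log2 fold change (vertical axis) of each of 60 interferon-stimulated genes in 5 comparisons (horizontal axis), 1 point per gene, sorted within a comparison, with the mean as a line. The mean was 1.61 for Dox in the sh225 line, -0.17 in the sh120 line, -0.19 in the Ctrl line and -0.53 for K26A against WT.

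The comparison of K26A with WT asks what the substitution in H1.4 changes. Each form was overexpressed in a single line, so other differences between these lines cannot be told apart from the substitution. Core histone genes were higher in K26A: 18 of 22 rose and 1 fell (20 and 1 adjusted over the list alone, mean 0.84, camera adjusted p = 2.50e-15, and adjusted p = 0.0134 with an estimated correlation of 0.158), with H4C8 at 1.71 ± 0.13 and H2AC8 at 1.49 ± 0.23. H1-2 was also higher, by 1.21 ± 0.15 (adjusted p = 1.62e-05). Histone genes are close copies, so a probe may read more than 1 of them. Interferon-stimulated genes were lower, 29 of 60 (35 lower and 2 higher adjusted over the list alone, adjusted p = 9.53e-12), with IFI27 at -2.05 ± 0.17, MX1 at -1.77 ± 0.10 and IFIT1 at -1.60 ± 0.16. OAS2 fell by 1.74 ± 0.11 and its other probes by less. Of 39 G1/S genes 28 fell (34 lower and 1 higher adjusted over the list alone, adjusted p = 8.92e-17), including RRM2 (-1.20 ± 0.15) and PRIM1 (-1.09 ± 0.11), and of 44 G2/M genes 24 fell (31 adjusted over the list alone, adjusted p = 3.44e-10). DNA repair genes were lower in 11 of 18 cases and higher in 1 (13 and 1 adjusted over the list alone, adjusted p = 1.14e-05). Sterol synthesis genes were lower in 14 of 23 and higher in 1 (16 and 1 adjusted over the list alone, adjusted p = 3.16e-06), with the desaturase SCD at -1.17 ± 0.10. Hypoxia and glycolysis genes were lower in 16 of 28 and higher in 1 (adjusted p = 1.04e-06), with the aldolase ALDOC at -1.37 ± 0.13 and the isomerase GPI at -1.06 ± 0.14. That list was higher in WT than in Ctrl (mean 0.32, camera adjusted p = 0.0104). It was not called in K26A against Ctrl (mean -0.08, camera adjusted p = 0.225). Luminal genes were lower in 12 of 34 and higher in 2 (16 and 2 adjusted over the list alone, adjusted p = 0.00027), including the prolactin receptor PRLR (-0.79 ± 0.12). ATF4 targets fell in 14 of 37 cases and rose in 3 (15 and 4 adjusted over the list alone, adjusted p = 0.0167, and adjusted p = 0.187 with an estimated correlation). That call was lost without K26 replicate 2 (adjusted p = 0.0648), with median centring (0.0508) and with all probes (0.0573). Among single genes, FGFBP2 was at least 3.23-fold and the chemokine receptor ACKR3 at least 3.30-fold higher. The cholesterol exporter ABCA1 rose by 1.61 ± 0.18 and CYP1A1 by 1.51 ± 0.21, while IL23A was at least 2.82-fold lower. Of 2208 genes, 1416 passed a log2 change of at least 0.5. The count was 1119 without WT replicate 1, 1338 without WT replicate 2 and 972 without K26 replicate 2.

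The WT line differed from the untreated Ctrl line in 3069 genes (1570 higher, 1499 lower), and K26A from Ctrl in 4962 (2335 higher, 2627 lower). Vector, culture and label set differed together with these groups. Besides H1-4, H1-2 was higher in WT by 1.48 ± 0.15 (adjusted p = 4.40e-07) and H1-10 by 0.50 ± 0.14 (adjusted p = 0.0118), the latter a call lost without Ctrl replicate 2 (adjusted p = 0.209) or WT replicate 1 (0.0689). The transmembrane glycoprotein GPNMB was higher in WT by 3.42 ± 0.16 and VTCN1 by 2.90 ± 0.17. The scavenger receptor CD36 was at least 4.81-fold higher and VCX2 at least 4.64-fold. VCX genes are near-identical, so their probes may share signal. Lower in WT were MT1X (-3.53 ± 0.12), CLIC6 (-3.16 ± 0.11), TRIM47 (-3.08 ± 0.12) and APOD (-2.89 ± 0.10). BDNF was at least 6.19-fold lower on its brightest probe, while its other probes ranged from -0.75 to 0.15. Serum response genes rose in 12 of 26 cases and fell in 1 (13 and 1 adjusted over the list alone, adjusted p = 0.000586), including JUN (1.52 ± 0.12) and ZFP36 (1.70 ± 0.16). Hypoxia and glycolysis genes rose in 12 of 28 and fell in 2 (12 and 4 adjusted over the list alone, adjusted p = 0.0104, and 0.0549 with all probes), with NDRG1 at 2.08 ± 0.17. NF-kappaB targets rose in 5 of 13 and fell in 1 (6 and 1 adjusted over the list alone, adjusted p = 0.00431). Metallothionein and oxidative stress genes fell in 7 of 15 (adjusted p = 0.000273).

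Further lists called in WT against Ctrl were not called with an estimated correlation, with the adjusted p given for each. Core histones rose in 16 of 22 cases (17 adjusted over the list alone, adjusted p = 0.0604 with an estimated correlation). Interferon-stimulated genes rose in 21 of 60 and fell in 7 (22 and 7 adjusted over the list alone, adjusted p = 0.0854), and antigen presentation genes rose in 6 of 18 and fell in 1 (adjusted p = 0.0972). Heat shock genes rose in 6 of 15 and fell in 1 (adjusted p = 0.164). Luminal genes fell in 14 of 34 and rose in 6 (16 and 6 adjusted over the list alone, adjusted p = 0.123), among them the progesterone receptor PGR (-1.22 ± 0.12) and its fellow estrogen target GREB1 (-1.29 ± 0.16). G2/M genes fell in 12 of 44 and rose in 4 (13 and 4 adjusted over the list alone, adjusted p = 0.215). The interferon-stimulated list also lost its call with probes detected on all arrays (adjusted p = 0.813), without background correction (0.167), with all probes (0.0858), with median centring (0.0678), and without WT replicate 1 (0.0563) or Ctrl replicate 1 (0.0515). Antigen presentation lost it without Ctrl replicate 2 (0.0993), with probes detected on all arrays (0.0941), without a filter (0.0863), without background correction (0.0836), with the replicate block (0.0518), without WT replicate 1 (0.0513) and with the series matrix aligned (0.0505). The G2/M call was lost without Ctrl replicate 1 (0.150), with median centring (0.0964), without WT replicate 1 (0.0717) and with the replicate block (0.0513). The luminal call was lost with median centring (0.0959) and without background correction (0.0860). In K26A against Ctrl, core histones rose in 19 of 22 cases and fell in 1 (20 and 1 adjusted over the list alone, adjusted p = 3.37e-12, and adjusted p = 0.0231 with an estimated correlation). G2/M genes fell in 35 of 44 and rose in 2 (adjusted p = 3.15e-07, and adjusted p = 0.0154 with an estimated correlation). Interferon-stimulated genes fell in 24 of 60 and rose in 5 (adjusted p = 0.00804, and adjusted p = 0.0461 with an estimated correlation). With the untreated sh225 line, whose arrays carry the same run of label numbers, as the control, 2356 of the 3069 genes (76.8%) were called again in the same direction for WT, and 4244 of 4962 (85.5%) for K26A. Both comparisons of a line use its same arrays, which adds to that overlap. The WT count was 1966 without Ctrl replicate 1 and 1835 without WT replicate 1.

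Without Dox the hairpin lines were close to Ctrl. The sh225 line differed in 44 genes (32 higher, 12 lower), a count that went to 1 without Ctrl replicate 1, to 145 without Ctrl replicate 2, to 20 without sh225 replicate 1 and to 0 without sh225 replicate 2 by limma (1383 at an unadjusted p under 0.05 with all arrays). The sh120 line differed in 2 genes, both lower and named after their values were seen: AKR1C2 (-0.88 ± 0.14) and the ribosomal protein gene RPL37, which was undetected on both sh120 arrays. That count was 66 without Ctrl replicate 2, 1 without sh120 replicate 1 and 0 without Ctrl replicate 1 or sh120 replicate 2 by limma, with 1084 at an unadjusted p under 0.05 with all arrays.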

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

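The tests of explanations for the rise of interferon-stimulated genes were chosen after that result was seen. What singled out each result is that the Dox effects of 2 lines differed in a test of the difference itself. Between sh225 and Ctrl 1571 genes differed, between sh120 and Ctrl 41, and between sh225 and sh120 1347. Of the genes named for a Dox effect in any line, 96, 12 and 91 were among them.

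The pattern weighed here is the rise of interferon-stimulated genes with Dox in the sh225 line. Doxycycline or the inducible vector alone is argued against by the Ctrl line, where the list had a mean log2 change of -0.19, with a mean difference of 1.80 between the lines. In the sh120 line, which carries another hairpin, the mean was -0.17 and the difference 1.78. That argues against expression of any hairpin only if the sh120 hairpin was expressed as strongly. Its target H1-4 was undetected in the hairpin lines, so this could not be checked. The sequence of the single sh225 hairpin stays open, since the series has 1 hairpin against several H1 variants and no second sequence to set beside it. Loss of H1 and another effect of that sequence cannot be told apart.

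Gene lists differed as well, given as mean log2 differences of the Dox effects. For sh225 against Ctrl, antigen presentation differed by 0.71, NF-kappaB targets by 0.94, metallothioneins by 0.84, p53 targets by 0.48, serum response genes by 0.46, ATF4 targets by 0.25 and ribosomal proteins by 0.17. The NF-kappaB difference held both a mean rise of 0.43 in the sh225 line and a mean change of -0.50 in the Ctrl line. The lower lists were G2/M at -1.39, G1/S at -0.94, fibroblast markers at -0.75 (S100A4 alone was called, 2 lower adjusted over the list alone), sterol synthesis at -0.74, DNA repair at -0.70 and heterochromatin at -0.27. Of these, fibroblast markers, ATF4 targets, ribosomal proteins and heterochromatin were not called with an estimated correlation (adjusted p = 0.0532, 0.116, 0.0745 and 0.0854). The fibroblast call was also lost without a filter (0.725), heterochromatin with probes detected on all arrays (0.0562) and ribosomal proteins without Ctrl_Dox replicate 2 (0.0543).

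For sh225 against sh120, the higher lists were antigen presentation at 0.81, NF-kappaB targets at 0.80, metallothioneins at 0.74, p53 targets at 0.56, serum response genes at 0.45, apoptosis at 0.27, ATF4 targets at 0.23 and ribosomal proteins at 0.21. The lower ones were G2/M at -1.06, fibroblast markers at -0.74, G1/S at -0.69, sterol synthesis at -0.67, DNA repair at -0.48, heterochromatin at -0.25 and glycolysis at -0.24. ATF4 targets and heterochromatin were not called with an estimated correlation (adjusted p = 0.0712 and 0.0531). For sh120 against Ctrl, G2/M differed by -0.33, G1/S by -0.25, DNA repair by -0.21, core histones by -0.21, heat shock genes by 0.23 and luminal genes by 0.14. Of these, DNA repair, core histones, heat shock and luminal genes were not called with an estimated correlation (adjusted p = 0.0532, 0.290, 0.133 and 0.112). All 4 also lost their calls without Ctrl replicate 1 (adjusted p = 0.0709, 0.150, 0.0806 and 0.0738). Other alternatives ended some of these calls as well, with the highest adjusted p, 0.174, for luminal genes without sh120_Dox replicate 2.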

How the results depend on the processing

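The counts of genes for the 3 Dox effects, the sh225 differences and the comparisons of WT and K26A stayed within 1.5 times of the main count under every alternative except the fold threshold and the leaving out of single arrays. A log2 change of at least 0.5 left 1059 genes for sh120 and 1416 for K26A against WT. With 1 array left out the lone array is assumed to vary like the other groups. The counts then ran from 2266 to 3261 for sh225, 651 to 825 for sh120, 133 to 314 for Ctrl, 972 to 1500 for K26A against WT, 1835 to 2489 for WT against Ctrl and 3981 to 4216 for K26A against Ctrl. They ran from 1096 to 1655 for sh225 against Ctrl, 945 to 1259 for sh225 against sh120, 1 to 26 for sh120 against Ctrl, and, without Dox, 0 to 145 for sh225 and 0 to 66 for sh120 against Ctrl.

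The small counts moved most, and the cause was not tested. The sh120 and Ctrl difference gave 101 genes without background correction, 67 with the series matrix (69 with its rows aligned), 24 without a filter and 17 with probes detected on all arrays. The untreated sh225 line gave 119 with median centring, 75 with the series matrix (74 aligned), 25 without a filter, 5 with probes detected on all arrays, and 29 with array weights. Its share of higher genes went from 72.7% to 83.1% without background correction. The untreated sh120 line gave 1 without background correction and 0 with median centring, without a filter, with probes detected on all arrays or with its label set alone.

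With the replicate block the counts were 3423 for sh225, 1577 for sh120, 275 for Ctrl, 2179 for K26A against WT and 3089 for WT against Ctrl. In WT against Ctrl the block ended the calls of 2 lists, antigen presentation (adjusted p = 0.0518) and G2/M (0.0513). Without Dox the block gave 71 genes for sh225 and 4 for sh120 against Ctrl. The numbers could not be shown to pair arrays: 8 of 16 arrays correlated best with another of their own number, and deviations correlated from -0.36 to 0.32. Crossed numbers, added after seeing the data, gave 264 genes for Ctrl, 3081 for WT and 4947 for K26A against Ctrl.

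Of 7050 values of 430 named gene results, 97.3% kept direction and side of the threshold. Most of these genes were picked for large called changes on the same arrays, which favours a high share. Genes dropped by a filter were not counted. The 4 reversals were all with the series matrix: CAPSL at 0.078 in the sh225 line, 0.081 against Ctrl and 0.062 against sh120, and HK1 at 0.031 in the last. The cause is the interchange of probe rows within genes: with rows aligned, added after seeing the data, CAPSL was -1.24, -1.25 and -1.99 and HK1 was -0.52. PSG6 lost its call in the Ctrl line under both versions. H1-2 in the sh225 line ran from -2.96 to -1.57, called each time, and H1-4 in WT against Ctrl was called each time. Of 75 list results 46 were called under every alternative. Weak signal over background limits dim genes: folds are bounds where all arrays of a group were undetected, and less certain than their SE where 1 of 2 was, as for H1-2 and HOATZ in the sh225 line and MYH11 in the sh120 line.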

Other observations

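In this part, the tests on the WT and K26A lines were chosen after the result was seen. The tests on the ciliary gene list were fixed before its values were seen, though after single ciliary genes had drawn attention, and its final make-up was set after a first run.

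Genes of motile cilia moved in opposite directions in the 2 lines with hairpins against H1. HOATZ fell by 3.14 ± 0.16 in the sh225 line, and FOXN4, a transcription factor of multiciliated cells, rose by 1.89 ± 0.15 in the sh120 line. To test whether this is a class of genes, a list of ciliary genes was drawn from general knowledge without those already noticed. After a first run, 4 noticed genes that had entered under older symbols were removed, which left 119 genes. Of 50 tested, 28 fell and 3 rose with Dox in the sh225 line (mean -0.69, camera p = 1.45e-09, adjusted p = 2.06e-04 with an estimated correlation). In the sh120 line 20 rose and 1 fell (mean 0.40, camera p = 1.39e-08, adjusted p = 2.42e-04 with an estimated correlation). In the Ctrl line limma called none, with 5 at an unadjusted p under 0.05. Of 8 comparisons tested, the list was also lower in WT than in Ctrl (17 fell and 3 rose, adjusted p = 0.00211) and was not called between K26A and WT (adjusted p = 0.650). The axonemal genes RSPH4A and TEKT1 fell by 2.13 ± 0.22 and 2.04 ± 0.22 in the sh225 line and rose by 1.23 ± 0.22 and 1.30 ± 0.22 in the sh120 line. These members were chosen after their values were seen. A high baseline of the untreated sh225 line as the whole cause is argued against: the list was also lower in sh225_Dox than in Ctrl_Dox (mean -0.31, camera p = 0.00338, adjusted p = 0.00965 with an estimated correlation). A higher baseline does go with part of the fall, since that mean was smaller in size than -0.69. With Dox in the Ctrl line the list changed by a mean of only -0.03, so it was on average higher in untreated sh225 than in untreated Ctrl. HOATZ was higher in untreated sh225 than in Ctrl by 1.20 ± 0.16. RSPH4A and TEKT1 were at -1.23 ± 0.22 and -1.25 ± 0.22 in sh225_Dox against Ctrl_Dox, also smaller in size than their falls with Dox. The difference of the sh225 and sh120 Dox effects was -1.09 on average, with 31 of 50 called. It includes the part that goes with the higher baseline of the untreated sh225 line. A hypothesis is that the 2 hairpins may act on this class in opposite directions. Whether through H1 is open: H1-2 fell beyond the Ctrl Dox effect in the sh225 line, while H1-4, the target in the sh120 line, was undetected in all hairpin lines. A second hairpin sequence per target, with H1 protein levels, would test it. The pattern was found and tested on the same arrays, and each line has 1 hairpin.

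The WT and K26A lines differed from Ctrl in 3069 and 4962 genes. The label set of the arrays as the cause is argued against, because WT differed in 3467 genes from the untreated sh225 line of its own set, and that line differed from Ctrl in 44. Culture or vector of the overexpression lines stays open: the series has 0 lines with that vector and no H1.4, so these cannot be told apart from H1.4 itself.

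Genes lower with Dox in the sh225 line and lower in K26A than in WT overlapped in 570 cases, against 228.0 for independent lists. Another 273 were higher in both, against 166.3. Opposite moves were fewer: 150 were higher with Dox and lower in K26A, against 211.1, and 89 the reverse, against 179.6. Across genes both effects correlated at r = 0.247. The interferon-stimulated list went opposite ways, with means of 1.61 and -0.53, while the cell cycle and sterol lists were lower in both. These comparisons share no arrays.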
